A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

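The series holds 26 libraries of budding yeast (Saccharomyces cerevisiae) in 13 groups of 2, per the labels. FKH1 and FKH2 encode Forkhead transcription factors, and the mutant strains are labelled with deletions of 1 or both of them. BrdU immunoprecipitation followed by sequencing was done in 10 libraries from 5 strains, labelled WT, fkh1Δ, fkh2Δ, fkh1Δfkh2Δ and fkh1Δfkh2Δ2C. Per the labels' protocols, cells in rich medium at room temperature were held with α-factor, the mating pheromone that stops a-type cells in G1, for 4 hours. They were then moved to medium with hydroxyurea, which lowers nucleotide supply and stalls replication forks, and BrdU, a thymidine analogue taken up into new DNA, for 1 hour. BrdU signal therefore gathers around the origins that fired in that hour. Strand-specific RNA sequencing after removal of ribosomal RNA, and chromatin immunoprecipitation of Rpb3, a subunit of RNA polymerase II, were each done in 8 libraries, which are WT and fkh1Δfkh2Δ2C, either growing asynchronously or held in G1 with α-factor for 4 hours.

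The authors deposited 3 tables, with a separate table for each assay and values for 241409 bins of 50 bp on 16 chromosomes. Per the file headers, the values are a normalized signal per bin. The aligner, the genome build and the method of normalization are not given in the sources used here. Read depth per library is unknown, so neither counting intervals nor detection floors could be given. Checked on the values, the libraries of an assay share nearly 1 distribution. The mean BrdU signal was 9.84 to 9.86 and its median 2.60 to 2.66, with the highest bin between 236.72 and 260.21. The mean Rpb3 signal was 45.3 in every library, the median 35.88 to 36.75 and the highest bin 3647.12. The highest RNA bin was 7823.69 in every library, and 72.4% to 83.2% of bins per strand column were listed at 0. Values normalized to a common distribution can show which places gained or lost relative to the rest of the genome, and cannot show a change of the total.

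The strains of the groups were taken from the strain tags, except for the second fkh2Δ BrdU library, whose strain was taken from its title. The second fkh2Δ BrdU library carries fkh1Δ in its strain tag while its title and source name say fkh2Δ. The double-mutant titles repeat fkh1Δ where the strain tags give fkh1Δfkh2Δ. The meaning of 2C is not given in the sources used here. Among the RNA columns, 2 carry the same name, for the forward columns of 1 asynchronous WT library, and were not used, so that genes on the Crick strand have 1 asynchronous library per strain and genes on the Watson strand have 2. No label states that the replicates of a group were separate cultures, so limma p-values measure the spread between these samples, which may be technical. Camera p-values set the genes of a list against other genes, and permutation p-values shuffle peaks or genes. Neither measures the spread between samples.

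Gene names, order, strands and lengths came from a RefSeq table of assembly R64, whose coordinates are not printed because the build of the files differs from it by small shifts. Each gene was placed in the files by fitting the R64 order, strand, length and spacing to the stranded RNA signal. This placed 5815 of 6002 protein-coding genes, and the fitted shift was within 1 bin for 96.1% of them. Most signal lay on the sense strand for 93.3% of the placed genes, against 83.0% and 82.9% when every gene was moved by 10 bins either way. Coordinates are 1-based and as in the files. Peaks of BrdU signal are given by chromosome and the centre bin, with the genes beside them, because names of replication origins and centromeres were not used here.

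BrdU peaks were local maxima of the highest of the 5 group means after smoothing over 1000 bp, at least 3 times the genome median of 2.70 and at least 5000 bp apart. This gave 388 peaks, each valued as the mean signal within 2500 bp. RNA and Rpb3 signal was averaged over 12063 windows of 1000 bp, per strand for RNA, and over placed genes. Windows were the unit fixed before the data were examined, and the gene-level fits were added after seeing the data, once genes could be placed. Values were tested as log2(signal + pseudocount) with limma 3.58.1 in R 4.3.3, in 1 fit per assay over all its groups with the variance trend on, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount was 10% of the median, which came to 1.98 for BrdU peaks, 0.0171 for RNA windows, 0.0797 for RNA genes, 3.90 for Rpb3 windows and 4.16 for Rpb3 genes. Fold changes are on the log2(signal + pseudocount) scale and understate the change of low genes. The lowest 10% of windows or genes were left out of the RNA and Rpb3 fits, leaving 21713 stranded RNA windows, 10856 Rpb3 windows and 5233 genes in each gene fit.

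Comparisons were each mutant against WT and fkh1Δfkh2Δ2C against fkh1Δ for BrdU, and for RNA and Rpb3 the mutant against WT within each stage, G1 arrest against asynchronous WT, and the difference of the strain effect between stages. Named genes were FKH1, FKH2, the 6 largest rises and falls past the threshold whose replicates did not overlap, and up to 2 members per list and direction with the smallest adjusted p, or the 2 with the smallest p where none passed. Named peaks were the 5 largest rises and falls past the threshold, or the 3 with the smallest p per direction.

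The 17 gene lists were written before the data were examined: the CLB2 cluster of G2/M genes, the SIC1 cluster of M/G1 genes, the MCM cluster, the G1/S cluster, histones, replication initiation, pheromone response, a-cell genes, α-cell genes, filamentous growth, stress, ribosome biogenesis, glycolysis, respiration, methionine, silenced loci and ribosomal proteins. In a list, 1 gene can also belong to another. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals, and fry, which asks whether the genes of a set move, on balance, one way and does not compare the set with other genes, were alternatives. For RNA the estimate and fry used only libraries with values on both strands, which leaves 1 asynchronous library per strain. Their RNA residuals thus came from the arrested libraries alone. The α-cell list was not tested, because 2 of its 4 genes were matched.

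Position classes (peaks within 20 kb of a chromosome end or of a centromere) were compared with other peaks by the difference of medians in a 2-sided permutation test with 100000 permutations. The centromere class, bounded by the first genes of either arm, was added after seeing the data. Similarity of mutants that share the WT libraries was set beside 1000 simulations of unchanged groups. The relation of BrdU changes to transcription changes within 500 bp used Pearson and Spearman correlations across peaks with permutation p. The spread of risen peaks around a monotone function of WT signal was compared with that between replicates, with 1000 bootstrap samples of peaks. Each fit was tested on simulated data with known changes. For fkh1Δfkh2Δ2C against WT, the BrdU fit on 388 peaks recovered 95.7% of 46 peaks changed 2-fold and 100% of 54 changed 4-fold, with 8 false calls. For the G1 comparison, the RNA gene fit on 5233 genes recovered 0.926% of 108 genes changed 2-fold and 9.78% of 92 changed 4-fold, and the Rpb3 gene fit 84.8% of 105 and 92.6% of 95, with 0 and 12 false calls. On 21713 stranded windows the RNA fit recovered 0% of 98 changed 2-fold and 0.980% of 102 changed 4-fold, and on 10856 windows the Rpb3 fit 86% and 92% of 100 each, with 11 false calls. In the simulated data a list of 33 genes raised 2-fold was recovered in both assays, with 4 false calls of other lists in RNA and 1 in Rpb3. How many other lists were tested there is not given here, so these calls give no rate for the gene lists above.

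Alternatives were other pseudocounts, filters, scalings, peak rules, a replicate block, fits on the compared groups alone, each library left out in turn, other list tests and other distances. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for everything outside limma, and the data.table package, version 1.17.8, read tables in R.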

Results

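The study followed where budding yeast replicates its DNA early after release from G1 in mutants of the Forkhead genes FKH1 and FKH2. It also followed how RNA and RNA polymerase II differ between a mutant of both genes and WT. The 26 libraries comprised 10 of BrdU-labelled DNA from 5 strains, 8 of stranded RNA and 8 of Rpb3-bound DNA, each group with 2 libraries. Signal is in the authors' normalized units per 50 bp bin, depth is unknown, and errors are SD over n = 2 libraries unless stated. Per the labels, WT was the control.

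The deleted genes were examined first. FKH1 carried a mean Rpb3 signal of 35.2 and 38.7 in the asynchronous WT libraries and 40.9 and 27.8 in arrested WT, against 1.88, 1.12, 7.02 and 1.80 in the 4 libraries of fkh1Δfkh2Δ2C. FKH1 RNA was listed at 0 in the mutant libraries and was 0.634 in asynchronous WT replicate 2 and 0.0830 and 0.256 in arrested WT. FKH2 was missing in part. In a stretch of 650 bp at its 3′ end (chromosome XIV, 495751 to 496400, coordinates as in the files, build not given in the sources used here), Rpb3 signal was 36.2, 39.7, 36.2 and 27.6 in WT and 1.21, 2.15, 4.31 and 2.33 in the mutant. Over the other 1800 bp of the gene it was 32.7, 38.1, 35.6 and 27.3 in WT and 55.1, 49.5, 61.3 and 54.5 in the mutant. The stretch was delimited from these Rpb3 libraries, and values over the whole gene therefore mix a missing and a present part. Measured that way, FKH2 had a log2 difference of 0.10 for asynchronous Rpb3 (limma adjusted p = 0.644) and 1.99 for arrested RNA (limma adjusted p = 0.387).

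The BrdU libraries carry DNA rather than transcripts, and genes labelled as deleted kept BrdU signal. BrdU values changed little between neighbouring bins, however. The median step was 0.641% to 1.04% of their mean over the BrdU libraries, against 17.4% to 20.9% over the Rpb3 libraries. Signal inside a deleted gene is therefore no evidence that its DNA was present. In fkh1Δ the signal inside FKH1 was 5.10 and 5.5, on a slope between 4.06 and 4.22 in the 1 kb to the left and 11.5 and 11.8 in the 1 kb to the right, and in WT it was 19.9 and 22.2 between 11.6 and 14.4 and between 33.5 and 35.1. It came to 65.4% and 68.7% of the mean of the flanks in fkh1Δ, 88.1% and 89.8% in WT and 91.7% and 87.0% in fkh2Δ, so these values neither show nor exclude the loss of FKH1 in the libraries labelled fkh1Δ. In fkh1Δfkh2Δ it was 2.79 and 2.62 (79.9% and 83.9%) and in fkh1Δfkh2Δ2C 2.81 and 2.70 (73.1% and 74.3%), below both flanks in these 4 libraries. At FKH2 the signal was 103% of the flanks in both WT libraries and 107% and 116% in fkh1Δ. In fkh2Δ it was 3.77 and 3.08, below both flanks, or 43.5% and 40.9%. The fkh2Δ library whose strain tag reads fkh1Δ thus dipped at FKH2 and had 20.6 inside FKH1. In fkh1Δfkh2Δ the value was 68.2% for replicate 1, whose 19.15 lay above its left flank of 18.7, and 39.6% for replicate 2, whose 9.80 lay below both. In fkh1Δfkh2Δ2C it was 96.8% and 62.4%. Over the 3′ stretch it was 91.1% and 77.4%, with replicate 2 alone below both flanks, against 88.2% and 91.5% in WT. The libraries of this label thus differed at FKH2, with a dip in replicate 2 and none in replicate 1, and since the meaning of 2C is not given, the label does not settle which gap they should carry. Replicate 1 is called the library labelled fkh1Δfkh2Δ2C replicate 1. The one with the intermediate value in fkh1Δfkh2Δ is called the library labelled fkh1Δfkh2Δ replicate 1.

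**Figure D1:**
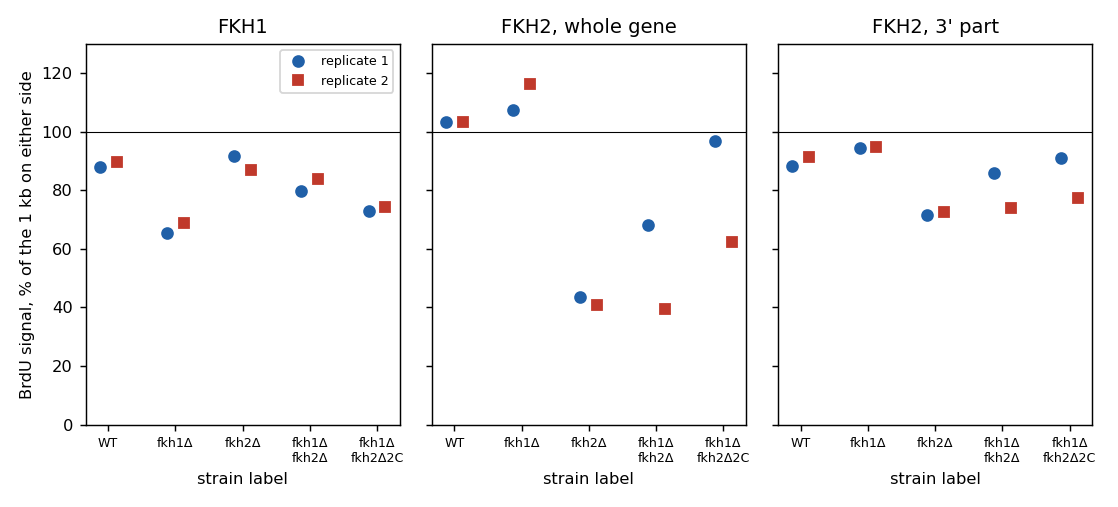
BrdU signal at FKH1, at the whole of FKH2 and at the 3′ part of FKH2, as percent of the signal in 1 kb flanks (y axis), for each BrdU library by strain (x axis). Circles are replicate 1, squares replicate 2 and the line marks 100; at FKH2 the fkh2Δ libraries lie at 43.5 and 40.9 and the WT libraries at 103.

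In fkh1Δ BrdU signal was lower at some origins and higher at others. Of 388 peaks, 84 rose and 123 fell in fkh1Δ against WT, in libraries whose own signal at FKH1 neither showed nor excluded the deletion. The largest fall was on chromosome XI at 55926, between EAP1 and TOR2, where signal was 11.7 ± 0.951 in fkh1Δ and 100.2 ± 12.2 in WT (log2 change −2.90, SE 0.150, limma adjusted p = 2.62e-07). The peak on chromosome II at 802126, between the maltose genes MAL33 and MAL31, went from 22.3 ± 3.80 to 1.96 ± 0.0634 (log2 change −2.62, limma adjusted p = 2.92e-07). The largest rise was on chromosome XIV at 411926, inside YNL115C, from 10.04 ± 0.840 to 41.3 ± 2.14 (log2 change 1.85, SE 0.126, limma adjusted p = 1.61e-06).

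Other named falls in fkh1Δ were on chromosome XVI at 418426 between YTA6 and UBP16 (−2.0), chromosome VII at 163126 between ATG1 and TOS3 (−1.86) and chromosome VII at 204376 between YGL159W and RCK1 (−1.76). Other named rises were on chromosome IV at 1447826 between SEC20 and LCD1 (1.69), chromosome XVI at 262126 inside RAD53, the checkpoint kinase gene (1.37), chromosome IV at 1240726 between NKP1 and ATO3 (1.12) and chromosome IV at 629576 between RLI1 and UBC13 (1.10). Of the peaks past the threshold, 32 fell and 9 rose by at least 1 on the log2 scale, and the median absolute change over all peaks was 0.44. Without fkh1Δ replicate 2, 55 peaks rose and 82 fell, a total of 137 against 207.

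In fkh2Δ no peak passed the threshold in limma, and 66 peaks had an unadjusted p under 0.05, 57 of them higher and 9 lower. The smallest p among higher peaks were on chromosome IV at 235226 inside PCL2, a cyclin gene (11.4 ± 1.01 against 6.52 ± 0.446, limma adjusted p = 0.108), and chromosome V at 317076 inside ICP55 (69.8 ± 4.72 against 46.5 ± 2.36, limma adjusted p = 0.108). The third was on chromosome XII at 1007276 between TSR2 and ECM30 (log2 difference 0.66). Among lower peaks they were on chromosome IV at 748526 between TAF12 and SWI5 (5.41 ± 0.399 against 9.64 ± 1.22, limma adjusted p = 0.0944), chromosome XI at 666426 beyond GEX2 (−0.41) and chromosome II at 79876 between NUP170 and ATG8 (−0.48). The median absolute difference over peaks was 0.17, near the median SE of 0.158. Replicate 2 of fkh2Δ held BAR1 signal of 2.55, against at most 0.0488 in the other 9 BrdU libraries and 0 in the 16 RNA and Rpb3 libraries, so that BAR1 appeared present in this library and absent from all others. It thus differed from WT and from fkh2Δ replicate 1 at BAR1 as well, and whether it came from another background strain is not given in the sources used here. Without it limma called 0 peaks, with 32 at an unadjusted p under 0.05, 28 higher and 4 lower. Without WT replicate 2, 1 peak rose, and with the mean taken within 5 kb 8 peaks passed.

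In fkh1Δfkh2Δ most peaks changed, and 160 peaks rose and 167 fell against WT, 84.3% of the 388. The largest fall was on chromosome XV at 1053576, between RDR1 and FRE3, where signal was 4.27 ± 0.443 against 111 ± 2.95 in WT (log2 change −4.18, SE 0.149, limma adjusted p = 1.69e-09). The peak inside DAL2, the allantoicase gene on chromosome IX, at 411826 held 7.07 ± 1.77 against 127 ± 10.4 (log2 change −3.85). The largest rise was on chromosome IV at 1110326, between ASP1 and MRPL35, with 39.5 ± 1.99 against 3.06 ± 1.00 (log2 change 3.06, limma adjusted p = 9.43e-08).

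Other named falls in fkh1Δfkh2Δ were the peak between EAP1 and TOR2 (−4.14), chromosome XII at 91726 between HSP104 and PAU17 (−3.89) and chromosome XIII at 31676 inside YML119W (−3.76). Other named rises were the peaks between SEC20 and LCD1 (3.05), inside RAD53 (2.94), inside YNL115C (2.90) and, on chromosome XV at 681426, between SER1 and GSP2 (2.74). By at least 1 on the log2 scale 110 fell and 81 rose. These values include the library labelled fkh1Δfkh2Δ replicate 1, which was close to a weighted sum of fkh1Δfkh2Δ replicate 2 and the library labelled fkh1Δfkh2Δ2C replicate 1, so the SD between the fkh1Δfkh2Δ libraries understates their error. Without it, 139 peaks rose and 159 fell.

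In fkh1Δfkh2Δ2C 178 peaks rose and 145 fell against WT. The peak between RDR1 and FRE3 fell from 111 ± 2.95 to 4.55 ± 1.10 (log2 change −4.13, limma adjusted p = 4.44e-09) and the peak inside DAL2 from 127 ± 10.4 to 11.97 ± 1.29 (log2 change −3.21, limma adjusted p = 8e-09). The peak between ASP1 and MRPL35 rose from 3.06 ± 1.00 to 43.0 ± 10.6 (log2 change 3.15, limma adjusted p = 9.33e-08) and the peak inside YNL115C from 10.04 ± 0.840 to 97.5 ± 9.36 (log2 change 3.05, limma adjusted p = 4.44e-09). The other named falls were between EAP1 and TOR2 (−3.74), inside YML119W (−3.35) and between HSP104 and PAU17 (−3.30). The other named rises were between SEC20 and LCD1 (3.11), inside RAD53 (3.0) and between SER1 and GSP2 (2.93). By at least 1 on the log2 scale 82 fell and 101 rose. These directions rest in part on the library labelled fkh1Δfkh2Δ2C replicate 1, which lacks the dip at FKH2. Without it, 193 peaks rose and 137 fell.

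**Figure D2:**
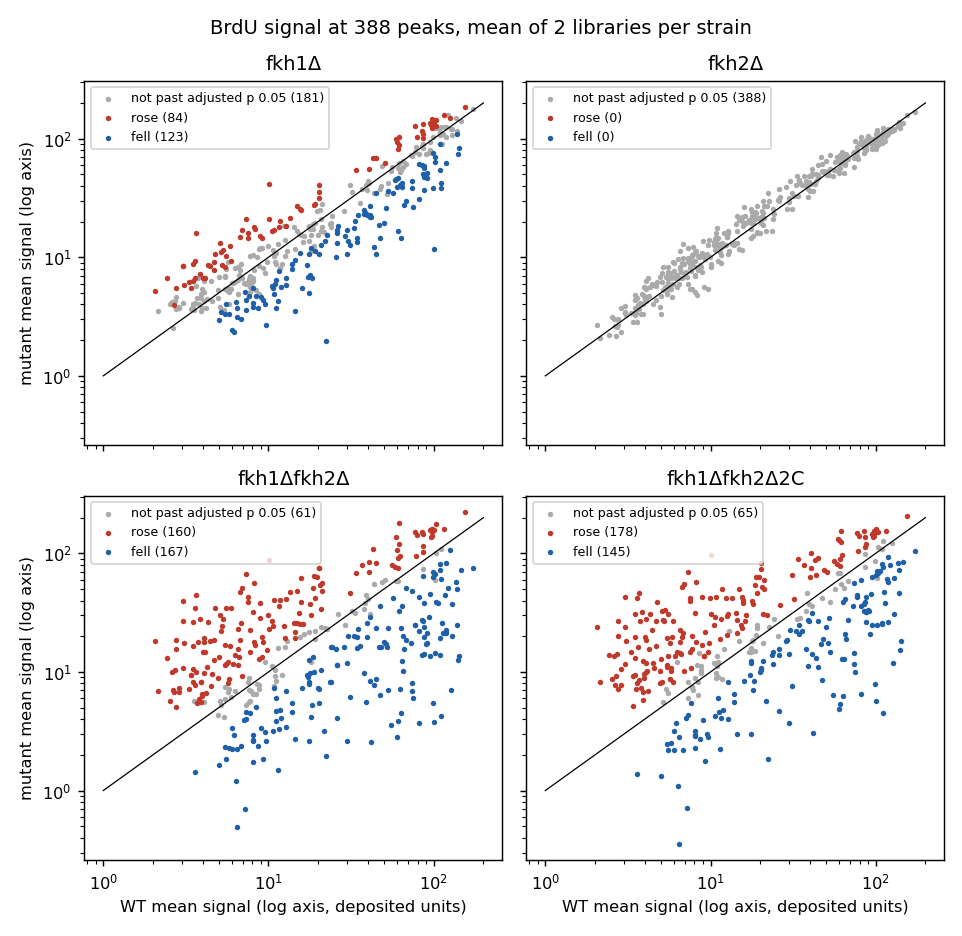
Mean BrdU signal of each of the 388 peaks in WT (x axis, log scale) and in a mutant (y axis, log scale), in normalized signal units, with a panel for each mutant. Red points rose and blue points fell at a limma adjusted p under 0.05 and grey points did not pass; 84 rose and 123 fell in fkh1Δ, none passed in fkh2Δ, 160 rose and 167 fell in fkh1Δfkh2Δ, and 178 rose and 145 fell in fkh1Δfkh2Δ2C, whose replicate 1 lacks the dip at FKH2.

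Against fkh1Δ, 184 peaks rose and 98 fell in fkh1Δfkh2Δ2C. The largest falls lay on the right arm of chromosome IX in a pair of neighbouring peaks that did not pass the test in fkh1Δ against WT. At DAL2 signal was 11.97 ± 1.29 in fkh1Δfkh2Δ2C and 120.5 ± 0.497 in fkh1Δ (log2 change −3.14, limma adjusted p = 7.22e-08), and at DAL1, the allantoinase gene (chromosome IX at 406776), 6.42 ± 2.29 and 53.1 ± 1.36 (log2 change −2.74, limma adjusted p = 4.39e-07). The log2 difference of fkh1Δ from WT at DAL2 was −0.07. Other falls were between RDR1 and FRE3 (−2.63), on chromosome II at 622976 between BEM1 and YBR200W-A (−2.58) and on chromosome IX at 247876 between YIL059C and RGI2 (−2.25). The largest rises were between ASP1 and MRPL35 (2.09), on chromosome II at 143476 at MIN6 (1.92), between SER1 and GSP2 (1.90), on chromosome XV at 729726 between NOC2 and RET1 (1.86) and on chromosome VII at 917426 at SLI1 (1.84). The library labelled fkh1Δfkh2Δ2C replicate 1 enters here too, and without it 216 peaks rose and 91 fell.

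The mutants shared many of the peaks that moved. In fkh1Δ and fkh1Δfkh2Δ2C 78 peaks rose in both (38.5 for independent lists) and 95 fell in both (46.0), with 9 opposite. The log2 changes had a Pearson r of 0.798 and a Spearman rho of 0.797 across peaks, with a covariance of 0.695. In fkh1Δfkh2Δ and fkh1Δfkh2Δ2C 156 rose in both (73.4), 141 fell in both (62.4) and 0 went opposite ways, with r of 0.979, rho of 0.976 and a covariance of 1.91. These groups share values beyond the WT libraries, since the library labelled fkh1Δfkh2Δ replicate 1 was close to a weighted sum that includes the library labelled fkh1Δfkh2Δ2C replicate 1, which lacks the dip at FKH2. Without the first r was 0.970, rho 0.968 and the covariance 1.95, and without both, on 1 library each, they were 0.947, 0.939 and 1.94, in alternatives chosen after seeing the data. In fkh1Δ and fkh2Δ r was −0.173 and the covariance −0.0258. Unchanged groups set against the same WT libraries gave a mean r of 0.498 and a covariance of 0.0170 in 1000 simulations. Covariances of 0.695 and 1.91 against 0.0170 argue against the shared WT libraries as the main source of these 2 similarities. The simulation used the spread between replicates, so controls that vary more than that would add more. The WT libraries were not split between comparisons, and peaks are not independent replicates.

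Peaks near chromosome ends lost signal in the mutants of both genes, and peaks near centromeres gained in fkh1Δ. None of the 9 peaks within 20 kb of an end rose in fkh1Δfkh2Δ2C and all 9 fell, and their median log2 change lay 1.69 lower than that of other peaks (−1.69, 2-sided permutation p = 0.00188, adjusted 0.00501 over 8 tests). In fkh1Δfkh2Δ the difference was −1.59 (permutation p = 0.00813, adjusted 0.0160) and 9 of 9 fell. In fkh1Δ it was −0.45 (permutation p = 0.104, adjusted 0.119), with 8 that fell and 1 that rose, and in fkh2Δ −0.03 (permutation p = 0.780). Within 40 kb of an end the fkh1Δ difference was −0.50 (permutation p = 0.00346). The fkh1Δfkh2Δ2C values rest in part on the library labelled fkh1Δfkh2Δ2C replicate 1.

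Of the 39 peaks within 20 kb of a centromere, 31 rose and 0 fell in fkh1Δ, and their median change was 0.44 against −0.15 for other peaks (difference 0.60, permutation p = 3e-05, adjusted 0.00024). The peak on chromosome III at 115026, between YCL001W-B and YCR001W, had a log2 change of 0.75 in fkh1Δ and 1.30 in fkh1Δfkh2Δ2C. The peak on chromosome XIV at 636126, inside SWM2, had 0.73 and 1.15. The peak on chromosome X at 417276, between RPC17 and NOP9, had 0.05, which did not pass, and −0.73. The difference was 0.88 in fkh1Δfkh2Δ (permutation p = 0.00999, adjusted 0.0160, 30 rose and 4 fell), 0.55 in fkh1Δfkh2Δ2C (permutation p = 0.0790, adjusted 0.105, 29 rose and 2 fell) and −0.17 in fkh2Δ (permutation p = 0.00053, adjusted 0.00212), where no single peak passed. The centromere class and the peaks named from it were chosen after seeing the data. The fkh1Δfkh2Δ difference had permutation p = 0.0721 within 10 kb, and that of fkh1Δfkh2Δ2C, which includes the library labelled fkh1Δfkh2Δ2C replicate 1, p = 0.0283 within 40 kb in the same permutation test.

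**Figure D3:**
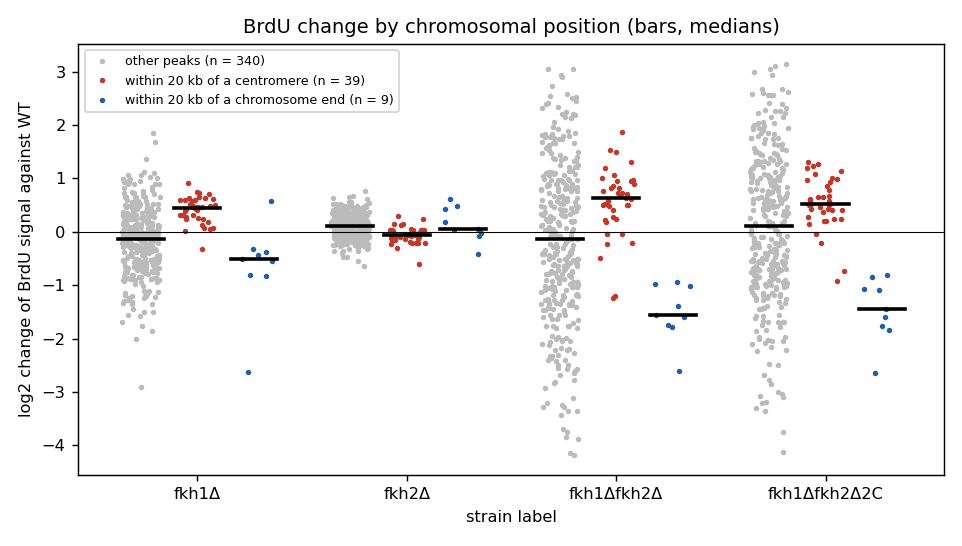
Log2 change of BrdU signal against WT (y axis) for each mutant (x axis), with peaks split into those within 20 kb of a centromere (39), within 20 kb of a chromosome end (9) and others. Points are peaks and bars are medians; the end class has medians of −0.51 in fkh1Δ, −1.55 in fkh1Δfkh2Δ and −1.45 in fkh1Δfkh2Δ2C.

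α-factor arrest of WT gave the reference for transcription. By camera the lists of pheromone response and a-cell genes stood higher in arrest, and those of histones and of the CLB2 and SIC1 clusters lower. Among genes, 41 rose and 68 fell for RNA and 123 rose and 61 fell for Rpb3. FIG2, a cell wall adhesin made during mating, rose in RNA from 0.403 ± 0.173 to 34.3 ± 4.55 (log2 change 6.20, limma adjusted p = 0.00172) and in Rpb3 from 28.3 ± 2.41 to 693 ± 69.8 (log2 change 4.42, limma adjusted p = 0.00149). EGT2, a cell wall gene of daughter-cell separation, fell in RNA from 4.89 ± 0.525 to 0.0939 ± 0.101 (log2 change −4.97, limma adjusted p = 0.00172) and in Rpb3 from 155 ± 16.2 to 25.1 ± 2.95 (log2 change −2.44, limma adjusted p = 0.00149).

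Of 27 pheromone response genes 16 rose in RNA (20 adjusted over the list alone) and 24 of 27 in Rpb3 (25 adjusted over the list alone), with medians of 2.22 and 1.92 (camera adjusted p = 1.34e-25 and 1.84e-35). PRM1, needed for fusion of mating cells, rose in RNA from 0.151 ± 0.0819 to 12.3 ± 2.33 and KAR4, a regulator of nuclear fusion genes, from 0.958 ± 0.121 to 15.2 ± 0.946. FUS1 rose in Rpb3 from 37.6 ± 0.418 to 249 ± 35.9 and AGA1, an agglutinin subunit, from 46.1 ± 14.9 to 818 ± 71.9. PRM8 (5.06), FIG1 (5.01) and SST2 (2.49) also rose in RNA, and FIG1 (3.37), PRM3 (3.30), PRM1 (3.11), SST2 (2.04) and FAR1 (1.53) in Rpb3. All 4 a-cell genes were higher in Rpb3, 2 past the threshold (4 adjusted over the list alone), with a median of 1.86 (camera adjusted p = 1.46e-06) and ASG7 and AGA2 at 2.31 and 2.5. In RNA 3 of 4 rose, the pheromone receptor gene STE2 from 5.36 ± 0.220 to 13.4 ± 3.52 (camera adjusted p = 2.96e-06 for the list).

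All 9 histone genes were lower in arrest, 6 past the threshold in RNA and 8 in Rpb3 (9 and 9 adjusted over the list alone), with medians of −2.45 and −2.06 (camera adjusted p = 7.29e-10 and 2.91e-12). HHT1, a histone H3 gene, went from 30.3 ± 4.14 to 6.59 ± 1.18 in RNA, and HHF1, a histone H4 gene, from 177 ± 50.6 to 26.3 ± 2.34 in Rpb3. HTA2 had a log2 change of −5.38 in RNA, where asynchronous cells had 1 library, and −2.21 in Rpb3. In the CLB2 cluster 9 of 33 genes fell in RNA (16 adjusted over the list alone, with 1 that rose) and 13 of 33 in Rpb3 (21 adjusted over the list alone), with medians of −1.24 and −0.37 (camera adjusted p = 3.44e-09 and 2.38e-14). CLB2, the main mitotic B-type cyclin gene, went from 1.62 ± 0.449 to 0.0670 ± 0.0225 in RNA (log2 change −3.52), and HST3 from 73.8 ± 5.22 to 27.3 ± 2.71 and CHS2, a chitin synthase of the septum, from 40.7 ± 0.679 to 23.4 ± 0.721 in Rpb3. In the SIC1 cluster 1 gene rose and 7 of 22 fell in RNA (3 and 16 adjusted over the list alone), with a median of −2.11, and 2 rose and 9 fell in Rpb3 (2 and 16 adjusted over the list alone), with a median of −0.59 (camera adjusted p = 6.76e-09 and 6.61e-10). SUN4, a septation gene, went from 8.12 ± 1.46 to 0.614 ± 0.167 in RNA, and PIR3 from 0.269 ± 0.0882 to 1.85 ± 0.331.

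In the G1/S cluster 7 of 31 genes fell in RNA and 5 of 28 in Rpb3, where 1 rose, with medians of −1.26 and −0.19 (camera adjusted p = 6.03e-07 and 3.51e-05). RNR1, the large subunit of ribonucleotide reductase, went from 2.65 ± 0.271 to 0.233 ± 0.133 in RNA, and the G1 cyclin gene CLN1 had changes of −3.17 in RNA and −1.01 in Rpb3. The Rpb3 call of the G1/S cluster had an adjusted p = 0.271 with an estimated correlation. Replication initiation genes had a median of −0.71 in RNA, with 1 that fell (camera adjusted p = 0.00928), and −0.03 in Rpb3 (camera adjusted p = 0.679), where CDC45 rose by 0.85. Respiration genes had a median of 0.41 in RNA (camera adjusted p = 1.47e-07) and −0.20 in Rpb3 (camera adjusted p = 0.0114, and adjusted p = 0.625 with an estimated correlation). Without asynchronous WT replicate 2 the camera adjusted p was 0.119 for replication initiation in RNA and 0.0547 for the G1/S cluster in Rpb3, and for respiration in Rpb3 it was 0.440 without asynchronous WT replicate 1 and 0.0578 without arrested WT replicate 2. The median over all RNA genes was −0.18, and list medians stand relative to it.

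Further lists passed camera in the arrest of WT and lost the call once the correlation was estimated. Stress genes had a median of 1.02 in RNA (camera adjusted p = 6.76e-09, and adjusted p = 0.0682 with an estimated correlation) and −0.79 in Rpb3 (camera adjusted p = 0.00101, and adjusted p = 0.625 with an estimated correlation). Ribosome biogenesis genes had −0.97 in RNA (camera adjusted p = 9.96e-07, and adjusted p = 0.342 with an estimated correlation) and 0.23 in Rpb3 (camera adjusted p = 0.00137, and adjusted p = 0.625 with an estimated correlation). Ribosomal proteins had −0.40 in RNA (camera adjusted p = 1.22e-06, and adjusted p = 0.165 with an estimated correlation) and 0.84 in Rpb3 (camera adjusted p = 8.33e-11, and adjusted p = 0.625 with an estimated correlation). Methionine genes had 0.95 in RNA (camera adjusted p = 5.2e-06, and adjusted p = 0.165 with an estimated correlation) and −0.36 in Rpb3 (camera adjusted p = 0.0899). Filamentous growth genes had −0.28 in RNA (camera adjusted p = 0.363) and 0.52 in Rpb3 (camera adjusted p = 0.00821, and adjusted p = 0.271 with an estimated correlation). Glycolysis genes had a median of −0.08 in RNA, with a mean of 0.22 of the other sign (camera adjusted p = 0.16), and −0.26 in Rpb3 (camera adjusted p = 0.0885). Asynchronous WT replicate 1 stood apart from the other Rpb3 libraries. Without it the Rpb3 medians were −0.35 for ribosomal proteins, −0.19 for ribosome biogenesis and 0.18 for methionine (camera adjusted p = 9.43e-13, 1.76e-04 and 0.00112), 0.06 for stress (camera adjusted p = 0.225) and 0.38 for filamentous growth (camera adjusted p = 0.127). Methionine and glycolysis had −1.01 and −0.42 in Rpb3 without asynchronous WT replicate 2 (camera adjusted p = 5.73e-08 and 0.0141), and glycolysis had 0.05 in RNA without arrested WT replicate 1 (camera adjusted p = 0.0475).

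Over windows of 1000 bp, 2 stranded RNA windows rose in arrest, at PRM1 (chromosome XIV, 111001 to 112000) by 6.16 and at KAR4 (chromosome III, 28001 to 29000) by 4.03, and 0 fell, with 3132 at an unadjusted p under 0.05 in limma. For Rpb3 260 windows rose and 135 fell. They included windows at FIG2 (chromosome III, 269001 to 270000, 4.64), AGA1 (chromosome XIV, 704001 to 705000, 4.21), EGT2 (chromosome XIV, 25001 to 26000, −2.54) and HHF1 (chromosome II, 255001 to 256000, −2.41). Without asynchronous WT replicate 1 or 2, 511 and 2040 Rpb3 genes passed, and without arrested WT replicate 1 or 2, 64 and 29 passed, while for RNA genes 15 to 37 passed without any 1 of the 4 WT libraries, against 109. Fitted on the WT libraries alone, 0 Rpb3 genes and 11 RNA genes passed.

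In asynchronous cells no single gene passed between fkh1Δfkh2Δ2C and WT, and the genes with the smallest p included daughter-cell separation genes of the SIC1 cluster. For RNA genes limma called 0, with 201 at an unadjusted p under 0.05, and for Rpb3 genes 0, with 1228. FKH1 was thus not among the calls, though its Rpb3 signal was 1.88 and 1.12 in the mutant and 35.2 and 38.7 in WT. It was either left out by the filter on low signal or not called. These counts of 0 therefore do not show that no gene changed. SCW11, a cell wall glucanase gene, had an Rpb3 signal of 37.2 ± 0.345 in the mutant and 112 ± 3.31 in WT (log2 difference −1.5, limma adjusted p = 0.114), and DSE2, another glucanase gene, 57.1 ± 5.11 and 115 ± 4.08 (limma adjusted p = 0.187). DSE2 RNA was 0.793 ± 0.25 and 2.80 ± 0.0262 (limma adjusted p = 0.900) and SUN4 RNA 3.13 ± 0.212 and 8.12 ± 1.46 (limma adjusted p = 0.940). Of 22 SIC1 cluster genes 4 were higher in the mutant in RNA, with a median of −0.31 (0 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.81e-04). In Rpb3 5 of 22 were higher, with a median of −0.30 (6 fell adjusted over the list alone, camera adjusted p = 0.00249, and adjusted p = 0.710 with an estimated correlation). Without asynchronous WT replicate 2 the camera adjusted p of this list was 0.111 in RNA and 0.0618 in Rpb3. SCW11 and DSE2 passed for Rpb3 without asynchronous WT replicate 1 (limma adjusted p = 0.00873 and 0.0247) or replicate 2 (limma adjusted p = 3.57e-05 and 0.000108).

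Further lists passed camera in asynchronous cells, respiration and filamentous growth in RNA, and stress and glycolysis in both assays. Respiration genes were higher in the mutant in RNA for 35 of 40, with a median of 0.37 (camera adjusted p = 3.23e-05), and QCR8 at 11.1 ± 2.38 against 4.31 ± 0.341. In Rpb3 their median was −0.21 (camera adjusted p = 0.224). Filamentous growth genes had −0.35 in RNA, 2 of 13 positive (camera adjusted p = 0.00249), with PHD1 at 1.39 ± 0.177 against 2.45 ± 0.417, and −0.09 in Rpb3 (camera adjusted p = 0.729). Stress genes had 0.75 in RNA, 21 of 23 positive (camera adjusted p = 1.02e-04, and adjusted p = 0.253 with an estimated correlation), with HSP12 listed at 0 in WT. In Rpb3 they went the other way, with a median of −0.94 and 0 positive (camera adjusted p = 5.04e-05, and adjusted p = 0.765 with an estimated correlation). Glycolysis genes had −0.15 in RNA (camera adjusted p = 0.0360, and adjusted p = 0.253 with an estimated correlation) and −0.57 in Rpb3 (camera adjusted p = 0.00395, and adjusted p = 0.710 with an estimated correlation). The RNA medians of respiration, filamentous growth and glycolysis without asynchronous WT replicate 2 were 0.19, −0.28 and 0.03 (camera adjusted p = 0.111, 0.0646 and 0.92). Without asynchronous mutant replicate 1 that of stress was 0.17 (camera adjusted p = 0.134), and without replicate 2 that of glycolysis was 0.33 (camera adjusted p = 0.146). Without asynchronous WT replicate 1, the Rpb3 library that stood apart, the Rpb3 medians of stress, glycolysis and filamentous growth were −0.21, −0.47 and −0.20 (camera adjusted p = 0.00434, 4.19e-06 and 0.0331), and without replicate 2 that of respiration was −0.37 (camera adjusted p = 0.00209).

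For asynchronous Rpb3, ribosomal proteins were higher in the mutant in 129 of 130 genes, with a median of 1.44 (camera adjusted p = 1.68e-24, and adjusted p = 0.710 with an estimated correlation). RPS30B was 183 ± 11.9 against 43.1 ± 36.8. Ribosome biogenesis genes were higher in 35 of 35, with a median of 0.65 (camera adjusted p = 3.19e-14, and adjusted p = 0.710 with an estimated correlation), and methionine genes in 0 of 19, with −0.77 (camera adjusted p = 3.56e-05, and adjusted p = 0.745 with an estimated correlation). In RNA the same lists had medians of 0.07, 0.09 and −0.13 (camera adjusted p = 0.817, 0.584 and 0.249), and ribosomal proteins had 0.13 and −0.10 without asynchronous mutant replicate 1 or 2 (camera adjusted p = 0.0239 and 6.73e-05). Asynchronous WT replicate 1 stood apart in Rpb3, with a Spearman correlation across genes, which are not independent replicates, of 0.457 to 0.645 with the other 7 libraries, while WT replicate 2 had 0.930 and 0.906 with the asynchronous mutant libraries. Without WT replicate 1 the Rpb3 medians of ribosomal proteins, ribosome biogenesis and methionine genes were 0.23, 0.22 and −0.21 (camera adjusted p = 2.85e-22, 3.4e-12 and 0.00434), and 4 genes passed. Without WT replicate 2, which leaves replicate 1 as the WT library, they were 2.58, 1.07 and −1.39 (camera adjusted p = 8.77e-61, 9.43e-19 and 6.94e-10), and 2495 genes passed.

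Lists that did not pass camera in asynchronous cells included the CLB2 cluster, with medians of −0.04 in RNA and −0.10 in Rpb3 (camera adjusted p = 0.263 and 0.276), and the histones, with −0.21 and −0.40 (camera adjusted p = 0.168 and 0.149). The G1/S cluster had −0.05 and −0.01 (camera adjusted p = 0.196 and 0.809), replication initiation −0.06 and 0.01 (camera adjusted p = 0.398 and 0.243), pheromone response −0.11 and −0.05 (camera adjusted p = 0.196 and 0.579) and a-cell genes −0.50 and 0.03 (camera adjusted p = 0.0898 and 0.830). In Rpb3 the CLB2 cluster passed without asynchronous WT replicate 1 (−0.10, camera adjusted p = 0.0252) and histones without asynchronous mutant replicate 1 (−0.54, camera adjusted p = 0.0245). By windows limma called 0 for RNA, with 934 at an unadjusted p under 0.05, and 0 for Rpb3, with 2470.

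In G1-arrested cells genes of the CLB2 cluster, which Fkh2 regulates in G2/M, stood higher in fkh1Δfkh2Δ2C than in WT. Of 33 genes 32 were higher in RNA, with a median log2 difference of 0.92, and 32 of 33 in Rpb3, with a median of 0.30 (camera adjusted p = 5.54e-14 and 4.6e-41). CLB2 itself rose in RNA from 0.0670 ± 0.0225 to 1.42 ± 0.194 (log2 change 3.36, SE 0.336, limma adjusted p = 0.0220), against 1.62 ± 0.449 in asynchronous WT. In Rpb3 it was 51.1 ± 4.22 against 22.6 ± 1.60 (log2 difference 1.05, limma adjusted p = 0.208). By single genes 1 member rose in RNA (13 adjusted over the list alone) and 0 in Rpb3 (21 adjusted over the list alone). RAX2 Rpb3 was 59.95 ± 2.15 against 34.1 ± 0.867 (limma adjusted p = 0.208).

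Among RNA genes in arrest 2 rose and 1 fell in the mutant, with 433 at an unadjusted p under 0.05. Besides CLB2, AIM34 rose to 0.736 ± 0.249 and was listed at 0 in WT (limma adjusted p = 0.0392), and PTR2, the peptide transporter gene, fell from 5.65 ± 0.885 to 0.442 ± 0.0971 (log2 change −3.46, SE 0.291, limma adjusted p = 0.0117). For Rpb3 genes limma called 0, with 195 at an unadjusted p under 0.05. FKH1 was among the calls of neither assay. By windows limma called 0 for RNA and 0 for Rpb3, with 2161 and 413 at an unadjusted p under 0.05. The RNA gene count was 0 without any 1 of the arrested libraries, with a limma adjusted p of 0.181 to 0.499 for CLB2, 0.202 to 0.39 for AIM34 and 0.085 to 0.388 for PTR2, while 169 and 39 RNA windows passed without mutant G1 replicate 1 or 2. In fits on the arrested libraries alone 0 RNA genes and 18 Rpb3 genes passed, with a limma adjusted p of 0.0226 for CLB2 Rpb3.

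The SIC1 cluster was also higher in the arrested mutant, in 19 of 22 genes for RNA, with a median of 0.60 (3 rose adjusted over the list alone, camera adjusted p = 6.01e-04), and 18 of 22 for Rpb3, with 0.17 (1 rose adjusted over the list alone, camera adjusted p = 1.12e-06). Of its members, NIS1 RNA was 1.00 ± 0.0517 against 0.299 ± 0.110 (limma adjusted p = 0.298) and CYK3 RNA, a cytokinesis gene, 1.44 ± 0.325 against 0.513 ± 0.144 (limma adjusted p = 0.346). Without mutant G1 replicate 2 the RNA median was 0.70 (camera adjusted p = 0.107). Methionine genes were lower in 19 of 19 in RNA, with a median of −0.77 (camera adjusted p = 1.6e-08, and adjusted p = 0.215 with an estimated correlation), SAM2 at 1.88 ± 0.636 against 4.47 ± 0.425, and −0.15 in Rpb3 (camera adjusted p = 0.0515). Ribosome biogenesis genes were higher in 30 of 35 in RNA, with 0.67 (camera adjusted p = 7.34e-05, and adjusted p = 0.619 with an estimated correlation), and had 0.11 in Rpb3 (camera adjusted p = 0.0163, and adjusted p = 0.889 with an estimated correlation). Respiration genes had 0.12 in RNA (camera adjusted p = 0.614), with ATP20 at 3.74 ± 0.273 against 1.19 ± 0.484, and 0.12 in Rpb3, higher in 34 of 40 (camera adjusted p = 3.24e-04, and adjusted p = 0.889 with an estimated correlation). The G1/S cluster had 0.25 in RNA (camera adjusted p = 0.299) and 0.05 in Rpb3 (camera adjusted p = 0.0131, and adjusted p = 0.889 with an estimated correlation). Ribosomal proteins had 0.12 in RNA (camera adjusted p = 0.407) and 0.19 in Rpb3 (camera adjusted p = 0.0301, and adjusted p = 0.921 with an estimated correlation). Glycolysis genes had −0.15 in RNA (camera adjusted p = 0.0252, and adjusted p = 0.397 with an estimated correlation) and −0.13 in Rpb3 (camera adjusted p = 0.216). Without arrested WT replicate 2 the RNA medians of methionine, ribosome biogenesis and glycolysis genes were −0.19, 0.11 and −0.04 (camera adjusted p = 0.156, 0.708 and 0.54), and without mutant G1 replicate 1 that of glycolysis was −0.03 (camera adjusted p = 0.468). In Rpb3, ribosome biogenesis and ribosomal proteins had a camera adjusted p of 0.369 and 0.28 without arrested WT replicate 1 and 0.246 and 0.413 without mutant G1 replicate 2. The G1/S cluster had 0.0815 by camera without arrested WT replicate 2, and a median of −0.03 (camera adjusted p = 0.252) without mutant G1 replicate 1. In RNA ribosomal proteins passed without arrested WT replicate 1 (camera adjusted p = 0.0374) and the G1/S cluster without arrested WT replicate 2 (camera adjusted p = 0.022), and in Rpb3 methionine passed without arrested WT replicate 2 or mutant G1 replicate 1 (camera adjusted p = 0.032 and 0.0423).

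With all libraries, lists of the mating response and of S phase did not pass between the arrested strains. Pheromone response genes had medians of 0.03 in RNA and −0.07 in Rpb3 (camera adjusted p = 0.676 and 0.216), a-cell genes 0.08 and 0.06 (camera adjusted p = 0.651 and 0.808), histones 0.42 and 0.04 (camera adjusted p = 0.407 and 0.221) and replication initiation 0.26 and −0.01 (camera adjusted p = 0.299 and 0.801). The pheromone response median in RNA was 0.36 without mutant G1 replicate 1 and −0.21 without replicate 2 (camera adjusted p = 0.045 and 0.00165), and in Rpb3 −0.11 without arrested WT replicate 1 and −0.18 without mutant G1 replicate 2 (camera adjusted p = 0.00204 and 8.13e-05). HHF1 RNA was 0.328 ± 0.0672 against 1.28 ± 0.306 (limma adjusted p = 0.3). Filamentous growth genes had −0.11 and −0.02 (camera adjusted p = 0.407 and 0.482), with TIP1 RNA at 7.81 ± 2.83 against 28.6 ± 9.16, and stress genes 0.15 and −0.01 (camera adjusted p = 0.888 and 0.808).

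**Figure D4:**
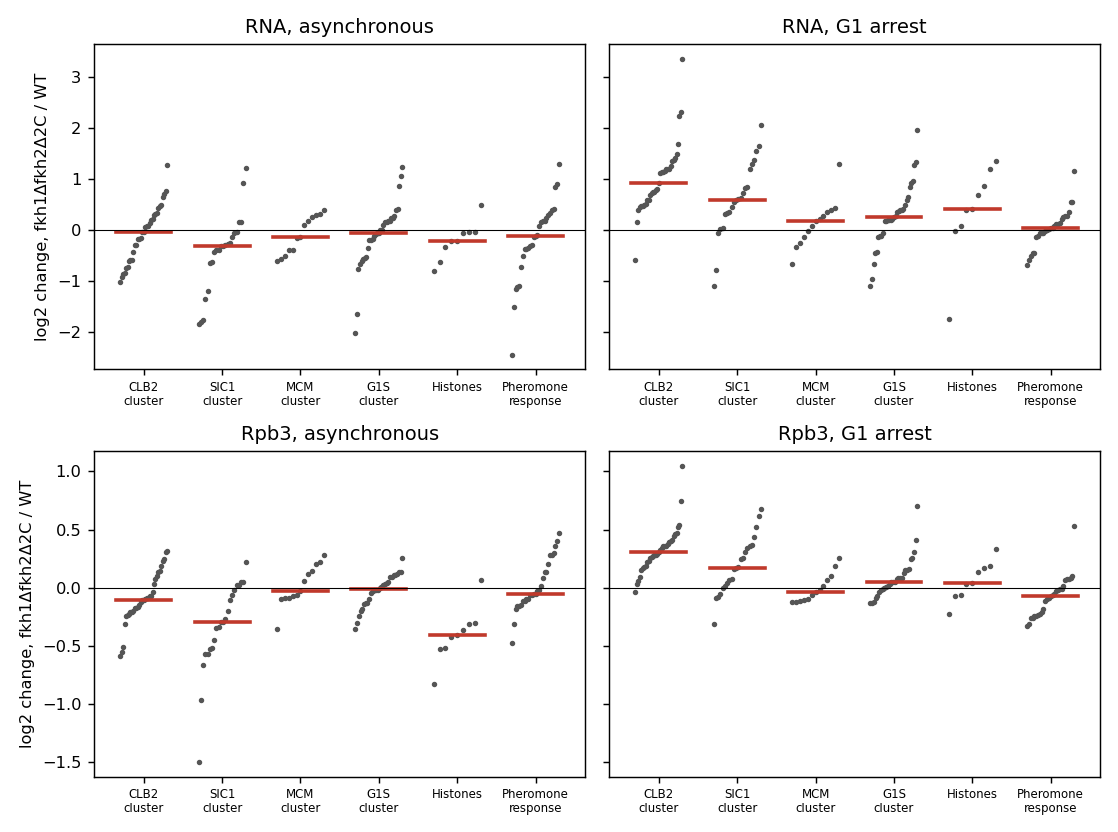
Log2 difference of fkh1Δfkh2Δ2C from WT (y axis) for each gene of 6 lists (x axis), in panels for RNA and Rpb3 and for asynchronous and G1-arrested cells. Dots are genes sorted by their value and red bars list medians; the CLB2 cluster has medians of −0.04 and −0.10 in asynchronous cells and 0.92 and 0.30 in arrest for RNA and Rpb3.

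The difference of the strain effect between arrest and asynchronous growth was tested directly. The CLB2 cluster had a median difference of 1.18 in RNA, positive in 29 of 33 genes (5 rose adjusted over the list alone, camera adjusted p = 4.89e-13), and of 0.33 in Rpb3, positive in 32 of 33 (13 rose adjusted over the list alone, camera adjusted p = 6.41e-18). The SIC1 cluster had 1.24 in RNA, positive in 20 of 22, and 0.50 in Rpb3, positive in 21 of 22 (camera adjusted p = 1.22e-08 and 4.24e-09). CLB2 had a difference of 3.50 in RNA (limma adjusted p = 0.377) and 1.25 in Rpb3 (limma adjusted p = 0.187), and SCW11, DSE2 and YML119W 1.5, 1.27 and 0.92 in Rpb3 (limma adjusted p = 0.187 each). Respiration genes had −0.28 in RNA, positive in 9 of 40 (camera adjusted p = 0.00610), with KGD2 at −1.27, and camera adjusted p = 0.258 without asynchronous WT replicate 2 and 0.0567 without asynchronous mutant replicate 2. By single genes limma called 0 in both assays, with 233 for RNA and 289 for Rpb3 at an unadjusted p under 0.05, and by windows 0, with 1239 and 654. Without asynchronous WT replicate 2, 1707 Rpb3 genes passed, and without replicate 1, 6 passed, with a limma adjusted p of 0.000343 and 0.0191 for CLB2. Without mutant G1 replicate 1 or 2, 612 and 33 RNA windows passed.

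Of the other lists in that test, the RNA calls of the G1/S cluster (median 0.38, camera adjusted p = 0.0415), stress (−0.69, camera adjusted p = 0.00181) and methionine (−0.67, camera adjusted p = 4.45e-04) each had an adjusted p = 0.374 with an estimated correlation, and ribosome biogenesis (0.55, camera adjusted p = 4.45e-04) had an adjusted p = 0.535 with an estimated correlation. The Rpb3 calls of histones (0.50), stress (0.95), ribosome biogenesis (−0.49), glycolysis (0.43), respiration (0.29), methionine (0.53) and ribosomal proteins (−1.25) each had an adjusted p = 0.547 with an estimated correlation. The Rpb3 medians without asynchronous WT replicate 1 were −0.06 for ribosomal proteins, −0.11 for ribosome biogenesis and 0.18 for stress (camera adjusted p = 7.27e-05, 7.27e-05 and 0.00635). For methionine, respiration and histones they were 0.06, 0.14 and 0.31 (camera adjusted p = 0.841, 0.191 and 0.0755). Without arrested WT replicate 2 the RNA medians of ribosome biogenesis and methionine were −0.02 and −0.07 (camera adjusted p = 0.94 and 0.468). The RNA call of the G1/S cluster was lost without any of 6 of the 8 libraries, all but arrested WT replicate 2 and mutant G1 replicate 1 (camera adjusted p = 0.0648 to 0.411). That of stress was lost without asynchronous mutant replicate 1, arrested WT replicate 2 or mutant G1 replicate 2 (camera adjusted p = 0.157, 0.0627 and 0.174). In Rpb3 the histone and glycolysis calls were lost without asynchronous mutant replicate 2 (camera adjusted p = 0.0744 and 0.0519), and that of glycolysis without arrested WT replicate 2 or mutant G1 replicate 1 (camera adjusted p = 0.0855 and 0.0703). Lists that passed in RNA with 1 library left out were histones without asynchronous WT replicate 2 or mutant replicate 2 (camera adjusted p = 0.0425 and 0.0207), glycolysis (−0.28) and ribosomal proteins (0.25) without asynchronous mutant replicate 2 (camera adjusted p = 0.00562 and 2.34e-04), and pheromone response (0.42) without mutant G1 replicate 1 (camera adjusted p = 0.00524). In Rpb3 they were the G1/S cluster without asynchronous WT replicate 1 or mutant G1 replicate 2 (camera adjusted p = 8.07e-05 and 0.037) and replication initiation without asynchronous mutant replicate 1 (camera adjusted p = 0.046). Pheromone response was −0.12 and −0.16 in Rpb3 without arrested WT replicate 1 or mutant G1 replicate 2 (camera adjusted p = 0.0104 and 0.00103). With all libraries, the MCM cluster and the silenced loci passed camera in none of the 8 RNA and Rpb3 comparisons, though without arrested WT replicate 2 the silenced loci passed in Rpb3 in arrest and in the difference (camera adjusted p = 0.00782 and 0.0143), with medians in arrest of 0.17 and 0.31 in RNA (camera adjusted p = 0.879 and 0.407). The camera calls that held with an estimated correlation were those of the CLB2 and SIC1 clusters in arrest and in the difference between stages, in both assays. In RNA they were also the SIC1 cluster, filamentous growth and respiration in asynchronous cells and respiration in the difference. In the arrest of WT they were the CLB2 and SIC1 clusters, histones, pheromone response and a-cell genes in both assays, and the G1/S cluster, replication initiation and respiration in RNA. The estimated RNA correlation was 0 for the CLB2 cluster, filamentous growth, histones and replication initiation, 0.00777 for the SIC1 cluster and 0.01 for respiration. These estimates rest on the residuals of the arrested libraries alone, and negative ones were set to 0. For these lists the RNA test with an estimated correlation was hardly stricter than the preset of 0.01.

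BrdU changes in fkh1Δfkh2Δ2C were compared with transcription changes within 500 bp of the 388 peaks, and 1 of 4 relations, that to asynchronous Rpb3, passed after adjustment. For asynchronous Rpb3, Pearson r was 0.185 (permutation p = 0.00036, adjusted 0.00144) and Spearman rho 0.146 (permutation p = 0.00455, adjusted 0.0182), with r of 0.181 without the 2 peaks farthest from the median. Without asynchronous WT replicate 1, the Rpb3 library that stood apart, r was 0.120 (permutation p = 0.0188) and rho 0.0849 (permutation p = 0.0963). For arrested Rpb3, r was −0.105 (permutation p = 0.0388, adjusted 0.0703) and rho −0.0994 (permutation p = 0.0511). For asynchronous RNA, r was 0.0981 (permutation p = 0.0527, adjusted 0.0703) and rho 0.0827 (permutation p = 0.105), and for arrested RNA r was −0.0766 (permutation p = 0.135) and rho −0.0710 (permutation p = 0.166). Without the 2 farthest peaks these were −0.106, 0.0954 and −0.0838. Peaks are not independent replicates, and the library labelled fkh1Δfkh2Δ2C replicate 1 enters each relation. The relation to asynchronous RNA rests on 1 RNA library per strain. Within 2.5 kb of the peaks r for arrested Rpb3 was 0.0846 (permutation p = 0.0976).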

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

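Of the tests in this part, the comparison of the share of the WT drop that was missing in the mutant was chosen after the result was seen, as were the gene-level fits that the lists rest on and the lists with a library left out, while the comparison with random lists was written down before its result was seen.

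The difference itself was tested with camera, which sets a list against other genes and does not measure the spread between samples. Fry, which rests on that spread, passed fewer lists for the RNA difference than camera with an estimated correlation did. By camera the effect of the mutant differed between stages for the CLB2 and SIC1 clusters in both assays and for respiration genes in RNA. These are the camera calls that held with an estimated correlation, and further lists passed at the preset correlation and not with an estimated one. The RNA estimates for the CLB2 cluster, the SIC1 cluster and respiration, from the arrested libraries alone, were 0, 0.00777 and 0.01. In RNA that test was thus hardly stricter than the preset of 0.01 for them. For the CLB2 cluster the camera adjusted p of the difference between arrested and asynchronous cells was 4.89e-13 in RNA and 6.41e-18 in Rpb3. For the SIC1 cluster it was 1.22e-08 in RNA and 4.24e-09 in Rpb3. For respiration genes it was 0.00610 in RNA, with a lower strain effect in arrest, and without asynchronous WT replicate 2 the median difference was −0.05 (camera adjusted p = 0.258).

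A candidate explanation for the higher CLB2 cluster in the arrested mutant is that some of its cells had left the arrest. If they cycled like asynchronous cells, histone and G1/S transcription would come back alike. In Rpb3, of the drop that 13 genes of the cluster showed in arrested WT, a median of 49.1% was missing in the mutant (16.9% to 102%). The median was 3.23% (−2.85% to 66.1%) for 13 histone and G1/S genes, and a 2-sided permutation test over genes gave p = 0.00242. These values argue against cells that left the arrest and cycled like asynchronous ones as the whole cause. The test cannot address cells outside G1 that were not spread over the cycle, and genes are not independent replicates. The asynchronous WT Rpb3 library that stood apart entered both the choice of these genes and their shares. The test was not repeated without that library. Low RNA signal in arrested WT, with more bins listed at 0, might also raise a median. The cluster's median of 0.92 lay at percentile 100 of 10000 random lists, whose highest median was 0.58. Those lists were matched on mean signal over all RNA libraries and not on arrested WT, where the cluster stood lower than in asynchronous cells. Low signal in arrested WT is therefore not excluded. In this mutant FKH2 was missing only in part. A difference between the strains stays open and untested, including the hypothesis that CLB2 cluster genes may be less repressed in G1 in the mutant. So do an incomplete arrest of the mutant, a part of the RNA median that comes from low signal, and any difference between the cultures.

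BAR1, the gene of the protease that degrades α-factor, held a mean BrdU signal of 2.55 in the second fkh2Δ library, above the highest value of 0.0488 among the other 9 BrdU libraries and the value of 0 in the 16 RNA and Rpb3 libraries. The same library carries fkh1Δ in its strain tag, and whether its background strain differs was not tested. BAR1 was outside the comparisons made here.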

How the results depend on the processing

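Of the tests in this part, the gene-level fits, the centromere class, the lists with a library left out and the lists under each gene-fit setting were chosen after seeing the data, as were the BrdU fit and the similarity of mutants without the library close to a mixture, and the remaining alternatives were set beforehand.

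Depth is unknown and each group has 2 libraries, so leaving out a library leaves an arm with 1 sample that is assumed to vary like the other groups. Of the pairs of an alternative and a result that answers a comparison, 318 stayed the same and 79 counts moved. A further 4 came to pass the threshold, 4 no longer passed and 1 reversed. Counts of calls stayed the same if they lay within 1.5 times of the main count or if neither held a call, whichever features were called. They moved if they lay further off or if only 1 of them held any call. Position classes and relations to transcription stayed the same if they kept their direction and their side of a permutation p of 0.05. Of such pairs for single genes, peaks, lists and the similarity of mutants, 1897 stayed the same, 44 came to pass, 111 no longer passed, 12 reversed and 1 moved, an r of 0.947 against 0.979. Most lists that passed neither with all libraries nor with 1 left out were counted as the same whatever their sign. The reversed ones were list medians with 1 library left out, which ranged from −0.26 to 0.33 for glycolysis RNA in asynchronous cells, −0.10 to 0.13 for ribosomal protein RNA in those cells, −0.018 to 1.08 and −0.28 to 0.18 for ribosome biogenesis and glycolysis RNA in the difference, −0.21 to 0.36 for pheromone response RNA in arrest, −0.11 to 0.21 for glycolysis RNA between stages of WT and −0.027 to 0.14 for the G1/S cluster Rpb3 in arrest. For Rpb3 between stages of WT they ranged from −1.62 to 0.060 for stress, −1.01 to 0.18 for methionine, −0.19 to 0.68 for ribosome biogenesis and −0.35 to 2.02 for ribosomal proteins. The CLB2 cluster passed in arrest and in the difference between stages in both assays under every gene-fit setting and with every library left out. For CLB2 RNA in arrest the limma adjusted p of 0.0220 became 0.12 in a fit on its own libraries, 0.152 with a pseudocount of the median and 0.0589 with no filter. Where a value below differs, the cause was not tested, except that fits on fewer libraries or windows test with fewer samples or features.

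Replicate numbers were checked for pairing by the correlation of deviations from group means. It was −0.541 to 0.33 over 10 BrdU pairs, −0.00717 to 0.138 over 6 RNA pairs and 0.0112 to 0.464 over 6 Rpb3 pairs, with 3, 2 and 4 above 0.1. Not every pair lay above 0.1 in any assay, so the numbers were not taken to pair the libraries, although all 6 Rpb3 values were positive. For Rpb3, WT and mutant of the same stage had 0.38 in asynchronous cells and 0.464 in arrest, so pairing within a stage is not excluded there. With the replicate number as a block, 27 RNA windows passed between arrested and asynchronous WT, against 2.

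For peaks in fkh2Δ, 4 passed with a pseudocount of the median, 1 after quantile normalization and 8 with the mean within 5 kb, against 0. For RNA windows between arrested and asynchronous WT, 2491 passed in a fit on those libraries alone, 34 with a pseudocount of the median, 11 with 1/100 of it, 280 after quantile normalization, 602 with no filter and 154 with the lowest 30% left out. For RNA windows of the mutant in arrest, 6, 19 and 4 passed after quantile normalization, with no filter and with the lowest 30% left out, against 0. For the difference between stages, 1 and 334 passed after quantile normalization and with no filter, and in asynchronous cells 323 with no filter, against 0 each.

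For RNA genes in arrest, 0 passed on own libraries, 1 with a pseudocount of the median, 7 with 1/100 of it and 0 with no filter, against 3. Between arrested and asynchronous WT 11 passed on own libraries, against 109. With no filter 45 passed in asynchronous cells and 48 in the difference, against 0. For Rpb3 windows on own libraries 39 passed in arrest, against 0, and 82 between stages of WT, against 395, and 1 passed in asynchronous cells with a pseudocount of the median. For Rpb3 genes on own libraries 18 passed in arrest, against 0, and 0 between stages of WT, against 184.

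With an estimated correlation, and by fry, 3 and 0 lists passed for asynchronous RNA (against 5), 2 and 1 for arrested RNA (against 5), 3 and 1 for the RNA difference (against 7), 0 and 0 for asynchronous Rpb3 (against 6), 2 and 1 for arrested Rpb3 (against 6), 2 and 2 for the Rpb3 difference (against 9) and 5 and 6 for Rpb3 between stages of WT (against 11). Near ends within 40 kb, the fkh1Δ difference was −0.50 and came to pass. Near centromeres, that of fkh1Δfkh2Δ within 10 kb was 0.87 and no longer passed, and that of fkh1Δfkh2Δ2C within 40 kb was 0.60 and came to pass. The relation of BrdU to arrested Rpb3 was 0.0846 within 2.5 kb, reversed from −0.105.

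With each library left out in turn, BrdU peaks past the threshold ranged from 137 to 177 in fkh1Δ, 0 to 1 in fkh2Δ, 298 to 318 in fkh1Δfkh2Δ, 292 to 336 in fkh1Δfkh2Δ2C and 232 to 307 against fkh1Δ. RNA windows ranged from 0 to 0 in asynchronous cells, 0 to 169 in arrest, 0 to 612 for the difference and 0 to 1 between stages of WT, and RNA genes from 0 to 0, 0 to 0, 0 to 0 and 15 to 37. Rpb3 windows ranged from 0 to 4405, 0 to 0, 0 to 2947 and 91 to 3600, and Rpb3 genes from 0 to 2495, 0 to 0, 0 to 1707 and 29 to 2040, in that order. Asynchronous WT replicate 2 gave each of these highest Rpb3 counts when left out, and mutant G1 replicate 1 each of the highest RNA window counts in arrest and in the difference. Lists ranged from 1 to 5, 3 to 6, 4 to 8 and 10 to 13 in RNA and 6 to 8, 5 to 7, 7 to 11 and 9 to 12 in Rpb3. Relations to transcription ranged from 0.0898 to 0.106 for asynchronous RNA, −0.0903 to −0.0313 for arrested RNA, 0.120 to 0.206 for asynchronous Rpb3 and −0.134 to −0.0396 for arrested Rpb3. For asynchronous RNA, with 1 RNA library per strain in this relation, only BrdU libraries were left out, so that range does not cover the RNA libraries.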

Other observations

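In this part the tests on the variance left by the best pair of libraries and on the spread around a monotone function, the centromere class, and the choice of the 50 highest peaks were chosen after the results were seen; the test on steps between neighbouring bins and the rank correlation were written down before theirs.

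Of the 50 peaks with the highest signal in fkh2Δ, where 1 library differs at BAR1 (91.2 to 168.4), 8 rose and 39 fell in fkh1Δfkh2Δ against WT, with a median log2 change of −1.46, and 8 rose and 37 fell in fkh1Δfkh2Δ2C, with a median of −0.91. In fkh1Δ 10 rose and 18 fell, with a median of −0.11. Over all 388 peaks 167 fell in fkh1Δfkh2Δ and 145 in fkh1Δfkh2Δ2C, with medians of −0.03 and 0.20, and a set chosen for high signal leaves more room to fall than to rise. Signal at TRP1 in Rpb3 was 62.4 and 64.2 in asynchronous WT and 60.1 and 54.3 in arrested WT, against 143, 127, 180 and 134 in the libraries of fkh1Δfkh2Δ2C. Of the Rpb3 drop in arrested WT, the share missing in the arrested mutant was 102% for SRC1, 81.9% for NDD1, a coactivator of the CLB2 cluster, 72.7% for CLB2 and 16.9% for HST3. It was 66.1% for the linker histone gene HHO1, and 4.43% and 2.70% for the G1 cyclin genes CLN2 and CLN1.

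The BrdU library labelled fkh1Δfkh2Δ replicate 1 was close to 0.512 times fkh1Δfkh2Δ replicate 2 plus 0.494 times the library labelled fkh1Δfkh2Δ2C replicate 1. A candidate explanation is that its values or reads were built from both. Its steps between neighbouring bins correlated with those of the weighted sum at r = 0.998, above the highest value of 0.994 among libraries outside this trio. The sum left 0.0327% of its variance, against a lowest share of 0.294% outside the trio. That value first drew notice to the library and is no separate test, but it argues against a further independent culture that resembles both, whose own noise would leave more. How such a library might have come about was not tested, and a mixture of cells, DNA or reads stays open.

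Rises of BrdU signal at 178 peaks in fkh1Δfkh2Δ2C could come from the authors' normalization to a common distribution, which raises what did not fall and would lift peaks of a like WT signal alike. Around a monotone function of a WT library, a mutant library had a spread of 0.55 to 0.63 on the log2 scale over these peaks, against 0.20 to 0.27 between replicates. The smallest over the largest came to 2.03 (95% bootstrap interval over peaks 1.70 to 2.46). These values argue against the normalization as the whole cause only if cultures of different strains vary no more than these replicates, whose spread may be technical. A part that it adds to the rises stays open, since the rank correlation of WT and mutant signal was 0.805, between the 0.957 of the WT replicates and the bound set for a changed order, and totals are unknown. The fkh1Δfkh2Δ2C libraries had 0.962 between them, and 1 of the 2 is the library labelled fkh1Δfkh2Δ2C replicate 1. No biological explanation of the rises was tested.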
